A study of Caenorhabditis elegans with 2 samples.

How the data were processed

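The samples were 2 biological replicates of eGFP-CEH-39 ChIP-seq from mixed-stage embryos of C. elegans strain OP169, with a library size range of 150 to 350 (unit not given) per the labels. The data used were 8 peak lists in the 10-column narrowPeak layout, 4 in each of the builds ce11 and ce10. Per the deposited description files, the relaxed list of each replicate was called on that replicate's alignments with a control, the pooled relaxed list on the alignments of both replicates with the same control, and the IDR list was derived from those 3 lists. The aligner, the peak caller and their versions are not given in the sources used here. The control was not analysed here.

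The signal value of each peak (column 7) is the authors' deposited value; its scale is not given in the sources used here, and it was used to rank, filter and describe peaks. The deposited −log10 q-value (column 9) was used as given to count peaks under a q-value of 0.05. Signal was compared between replicates by correlation or rank only. No read counts were used, so the depth of each sample is unknown.

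Peaks were read in ce11 for all main results. All peak ends lay within the chromosome lengths of the WBcel235 reference, the assembly that ce11 names, and gene models came from Ensembl release 115 of that assembly. The ce10 lists served only for alternatives that need no annotation, and no coordinates were converted. All 1244 IDR peaks were identical in position and signal to peaks of the pooled list, and were exactly the 1244 pooled peaks with a signal value of at least 76.5. Their −log10 q-values were tied at 3.52. The ce10 IDR list held 1241 peaks; 1233 of the ce11 peaks had a ce10 peak on the same chromosome with a signal value within 0.1%.

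A summit was assigned to the promoter window (1000 bp upstream to 200 bp downstream of any protein-coding transcript start), then to 5′ UTR, coding sequence, 3′ UTR, intron or intergenic sequence, in that order. Placements drew the same number of positions on each chromosome 100 times, and two-sided p-values from them cannot fall below 0.020. Shares on chromosomes were tested with exact binomial tests against shares of protein-coding genes. Motif matches were counted within 50 bp of the summit and in windows centred 350 bp away, and compared with exact McNemar tests on the lower-coordinate flank. The hexamer ranking merged both strands, ordered hexamers by that test's p-value and applied Benjamini-Hochberg adjustment. Flank shares printed for hexamers are means of both sides. Differences in median signal were tested with 100000 permutations. Peaks around the middle of ceh-39 were compared with those around 10000 positions drawn at the starts of other X genes; windows centred on starts, or on middles, for both were added after the data were seen. The interval of the rank correlation came from 1000 bootstrap draws of peaks. Overlap between lists needed at least 1 bp, with 100 shuffles within chromosomes as the background.

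The 17 gene lists, tests and alternatives were fixed before the data were examined, except where stated. Lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over lists. Of the list members given by symbol, elt-5 (epidermis) and daf-21 (heat shock) matched no gene name in the annotation and were left out. Some symbols stand for several near-identical gene records, 97 symbols in all; each record was counted. Named genes were xol-1 and every ONECUT member, every bound member of the sex determination and dosage compensation list, the genes with starts nearest to the 15 strongest IDR peaks, and for each other list up to 4 bound members with the highest signal if the list passed an adjusted p of 0.05 and up to 2 otherwise.

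Alternatives took the 1244 strongest peaks of each replicate alone, the 622 strongest IDR peaks, the 2488 strongest pooled peaks, or IDR peaks merged within 1 kb. Others changed the windows (500 or 2000 bp upstream, 25 or 100 bp around the summit, 500 bp around tRNA genes, 10 or 50 kb around ceh-39), the flank, the background, the build, the overlap rule (50% of the peak covered, or summits within 100 bp) and the assignment of peaks to genes. The functions were tested on simulated data. In 20 simulated sets of 1244 positions, ATCGAT planted in 15.0% of windows was called in 20 sets, while 0 sets without planting were called. In 20 simulated sets, a list with 12 added bound members was recovered in 20, and 0 null sets gave any list past the threshold. That list was the cell cycle list of 27 genes, of which 8 were bound in the data. Simulated genes were drawn independently and positions at random. The sets therefore do not show how often peaks shared by neighbouring genes, or promoter sequence, give false calls. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.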

Results

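Binding of CEH-39 to the genome of Caenorhabditis elegans was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mixed-stage, mixed-sex embryos. CEH-39 is a ONECUT homeobox protein, encoded on X, that is known as an X signal element acting on the sex-determination switch gene xol-1. The strain, OP169, carries an integrated transgene that expresses the factor fused to eGFP. The series held 1 group of 2 biological replicates, so the peak set was described against the genome and no treated and control groups were compared. The values were peak positions and the signal value that the authors' caller gave each peak; read counts were not used here, so sequencing depth is unknown. Intervals are 95% exact (Clopper-Pearson) intervals over peaks or genes and cover counting error only, since neighbouring peaks are not independent. Coordinates are in ce11, numbered from 1.

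IDR peaks of the eGFP-CEH-39 ChIP lay mainly at the starts of protein-coding genes. The authors' set thresholded by the irreproducible discovery rate (IDR) held 1244 peaks, and 933 of their summits, or 75% (interval 72.5 to 77.4%), lay between 1000 bp upstream and 200 bp downstream of a protein-coding transcript start. Random positions on the same chromosomes fell there in 25.8% of cases (SD 1.01 over 100 placements), a 2.91-fold difference (permutation p = 0.020, two-sided, the smallest that 100 placements can give). The median summit lay 193.5 bp upstream of the nearest start. Outside these windows, coding sequence held 1 summit, or 0.0804%, against 18.9% of placed positions. Introns held 105 summits, or 8.44% against 28.2%, and intergenic sequence held 198, or 15.9% against 24.4% (permutation p = 0.020 for each of these classes). In all, 1294 of 19973 protein-coding genes, or 6.48%, had an IDR summit in the window of a start and are called bound here.

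The 15 strongest peaks included 13 in promoter windows, among them those of histone and ribosomal protein genes. The highest signal value, 554, belonged to a peak on chromosome II from 11979725 to 11980095, with its summit 57 bp upstream of Y17G7B.20. The next peak (signal 516, chromosome I, 9988795 to 9989135) lay between the divergent histone genes his-67 and his-68, with its summit 168 bp upstream of his-68. Peaks 3 to 7 had their summits closest to the starts of C37A2.8 (signal 506), tos-1 (499), T26A8.4 (496), nono-1 (484) and K04G2.10 (476). Peak 8 (signal 449, chromosome IV, 4749962 to 4750183) stood between Y17G9B.5, the nearest start, and the ribosomal protein gene rpl-20. Others among the 15 strongest lay at tasp-1 (439), cdc-48.1 (431), which encodes an AAA ATPase of protein quality control, rpl-3 (430), sec-61.G (429), a subunit of the protein translocon, and set-10 (395), a SET-domain gene. The remaining 2 of the 15 were intergenic, with summits 2971 bp upstream of F07H5.13 (signal 444) and 3861 bp upstream of Y17D7C.2 (signal 420). Over the whole set the median signal value was 108 and the lowest 76.5, and 87.7% of peaks were 350 bp wide.

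Most IDR peaks had a peak in each replicate's relaxed list, but the lists of strongest peaks overlapped only in part. The his-67 and his-68 peak ranked 9 in replicate 1 and 2 in replicate 2 by signal value within each replicate's own list, and the peak at the ONECUT gene ceh-38 ranked 39 and 3043. Of the 1244 IDR peaks, 88.9% (interval 87.0 to 90.6%) were overlapped by at least 1 bp by the 1244 strongest peaks of replicate 1, and 57.5% (54.7 to 60.2%) by the 1244 strongest of replicate 2. Peaks shuffled within chromosomes gave 0.876% and 0.827%. Against the whole relaxed lists, which include background by construction and from which the IDR set was derived, the shares were 99.5% and 95.02%, with 19.9% and 17.1% after shuffling. The 1244 strongest peaks of replicate 1 overlapped those of replicate 2 in 50.2% of cases. Across the 1176 IDR peaks present in both lists, signal values correlated with Spearman's rho of 0.286 (95% bootstrap interval 0.230 to 0.341) and Pearson's r of 0.397 on the log2 scale. These are across peaks, which are not independent replicates. The IDR set is cut at a pooled signal value, so they describe the selected peaks only. Among the peaks of upper pooled signal rho was 0.264 (609 peaks), and among those of lower pooled signal it was -0.494 (567 peaks). Selection on pooled signal can lower such values, so they are not a direct measure of how far the replicates agree. Signal in the pooled list followed replicate 1 (rho 0.912) more closely than replicate 2 (rho 0.533). Peaks with a q-value under 0.05 numbered 3958 in replicate 1 and 790 in replicate 2. The 1244 strongest peaks of replicate 2, used here and below, therefore include some that miss this threshold.

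**Figure D1:**
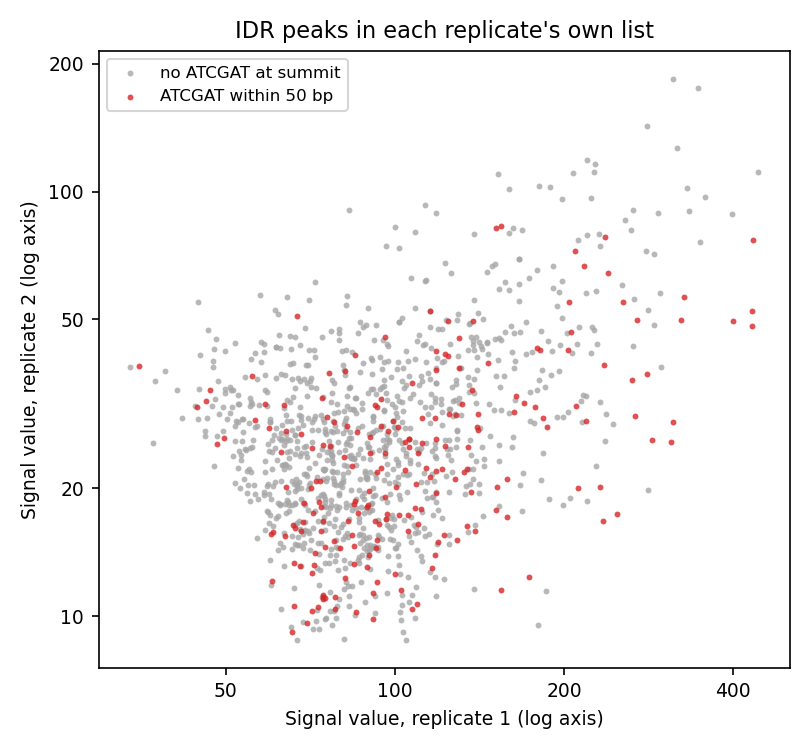
Signal values of the IDR peaks in each replicate's own relaxed list, on log axes, 1 point per peak (1176 peaks with a peak in both lists). Red points have ATCGAT within 50 bp of the summit; the rank correlation over all points is 0.286.

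Among the 17 gene lists tested, cytosolic ribosomal protein genes were bound most often. Of 79 members 60 were bound, or 75.9% (interval 65.0 to 84.9%), against 6.20% of other protein-coding genes, a 12.2-fold difference (two-sided Fisher's exact test, adjusted p = 6.06e-54). With each peak given only to its nearest start 34 were bound, or 43.04% (ratio 9.85), and with the strongest peaks of replicate 2 alone 45, or 56.96% (10.56). The ratio was 7.32 in the 2488 strongest pooled peaks and 18.4 in the 622 strongest IDR peaks. Their strongest peaks lay 299 bp upstream of rpl-20 (signal 449), 276 bp upstream of rpl-3 (430), 229 bp upstream of rps-20 (339) and 444 bp upstream of rpl-35 (322). Genes of the cell cycle and DNA replication were bound in 8 of 27 cases, or 29.6%, 4.60-fold above other genes (Fisher's exact test, adjusted p = 0.0013). They included mcm-7 (signal 124), a subunit of the replicative helicase, cye-1 (122), which encodes cyclin E, lin-35 (121), the retinoblastoma homologue, and cdc-6 (100.4), a replication licensing factor. In this order their peaks ranked 397, 292, 573 and 836 in replicate 1, but 3909, 11166, 435 and 1061 in replicate 2. With the strongest peaks of replicate 2 alone, 8 of 27 members of this list were bound (ratio 5.32). Among the 622 strongest IDR peaks alone the cell cycle list gave a 3.15-fold difference that did not pass (Fisher's exact test, adjusted p = 0.23).

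Histone genes were bound in 15 of 72 cases, or 20.8%, 3.24-fold above other genes (Fisher's exact test, adjusted p = 4.06e-04). The peaks between his-67 and his-68 (signal 516) and between his-31 and his-32 (357) led this list; the 72 gene records share 50 symbols, and near-identical copies make the assignment of peaks to single histone genes uncertain. With each peak given only to its nearest start, the histone list no longer passed (Fisher's exact test, adjusted p = 0.054). Nuclear hormone receptor genes were bound less often than other genes, in 6 of 269 cases, or 2.23%, a ratio of 0.341 (Fisher's exact test, adjusted p = 0.010). The bound members with the highest signal were nhr-47 (126), nhr-86 (91.7), nhr-34 (87.8) and nhr-49 (87.7). This list did not pass with a window of 500 bp upstream (ratio 0.413, Fisher's exact test, adjusted p = 0.082) or with nearest-start assignment (ratio 0.490, adjusted p = 0.21).

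The other 13 lists did not pass the threshold. Heat shock and chaperone genes were bound in 3 of 13 cases (ratio 3.57, Fisher's exact test, adjusted p = 0.12), among them hsp-1 (signal 271), which encodes the constitutive Hsc70, and hsp-3 (232), an endoplasmic reticulum chaperone. Collagens were bound in 4 of 156 cases (ratio 0.394, Fisher's exact test, adjusted p = 0.12), with col-2 (191) and col-38 (167) the strongest. Heat shock genes did pass with the strongest peaks of replicate 2 alone (ratio 6.90, Fisher's exact test, adjusted p = 0.0020), in the 622 strongest IDR peaks (6.55, adjusted p = 0.041) and in the 2488 strongest pooled peaks (3.95, adjusted p = 0.0060). Collagens passed with the strongest peaks of replicate 1 or 2 alone (ratios 0.297 and 0.228), in the 2488 strongest pooled peaks (0.218) and with nearest-start assignment, where none was bound (Fisher's exact tests, adjusted p = 0.047, 0.037, 1.74e-04 and 0.0081). Of tissue lists, pan-neuronal genes had 2 of 19 bound (snb-1, signal 113, and syd-2, 96.6), body wall muscle 1 of 20 (unc-112, 79.1), germline and P granule 1 of 21 (mex-1, 150.2), and Wnt and Notch signalling 1 of 20 (sys-1, 111). The unc-112 peak was not overlapped by any peak of the relaxed list of replicate 2. No member was bound among 11 endoderm and intestine genes, 14 epidermis genes, 8 pharynx genes and 6 Hox genes. With lists of this size a share of up to 28.5%, 23.2%, 36.9% and 45.9%, respectively, lies within the interval. Homeobox genes as a whole had 5 of 63 bound (ratio 1.23), led by ceh-38 (268) and ceh-20 (128), but 1 of 63 with the strongest peaks of replicate 2 alone (ratio 0.283). In that set pan-neuronal genes had 1 of 19 bound (ratio 0.940, against 1.63).

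**Figure D2:**
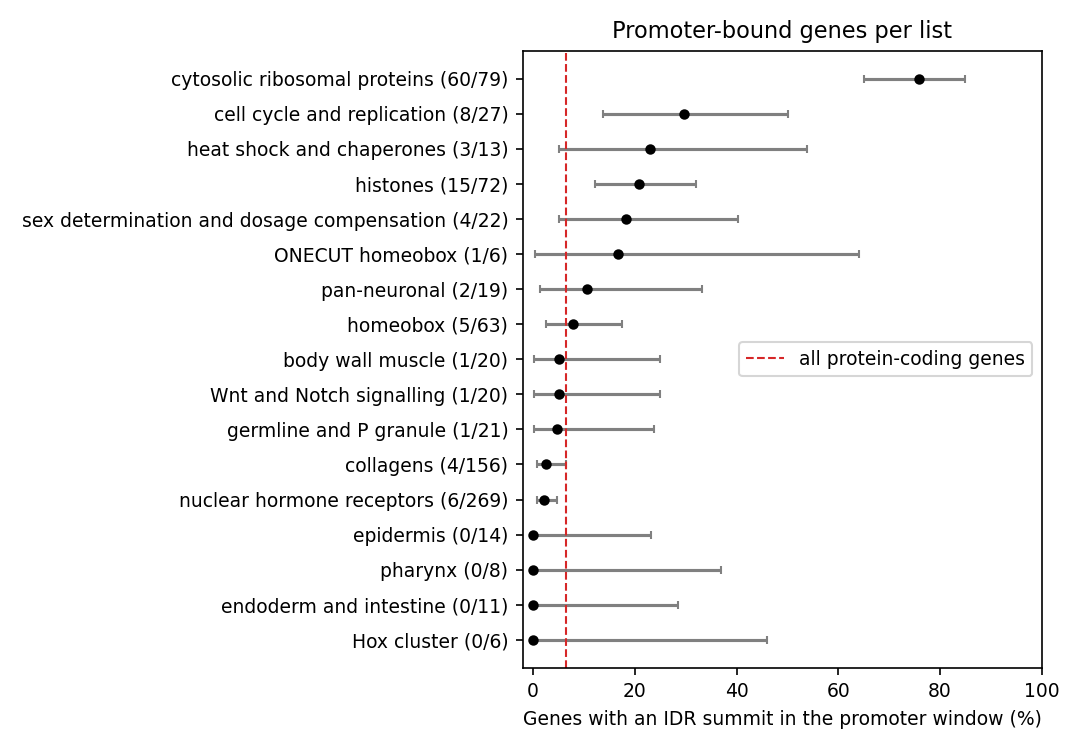
Share of each list's genes with an IDR summit in the promoter window, with exact 95% intervals and the numbers bound and measured; the dashed line marks all protein-coding genes (6.48%). Ribosomal protein genes stand at 75.9%.

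Because CEH-39 is known to act on xol-1, peaks around this gene were listed in every peak set. No IDR summit lay in the promoter window of xol-1 (X, 8041313 to 8044409, plus strand). The nearest IDR peak (X, 8036323 to 8036506) was intergenic, and its summit at 8036408 lay 4905 bp upstream of the xol-1 start, the nearest protein-coding start to it. It ranked 76 of 1244 with a signal value of 252, and 158 and 26 in the lists of replicates 1 and 2. It contained ATCGAT at 8036420 to 8036425, in the context AAAAAATTATCGATTTTTCCAT, and the near end of a tRNA gene lay 277 bp from its summit. Closer to the gene the pooled relaxed list held a peak 829 bp upstream, at rank 9204 of 30000 with a signal value of 25.8 and a -log10 q of 0.0987. The relaxed lists of replicates 1 and 2 held peaks 663 and 842 bp upstream, at ranks 7753 and 10555.

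Of the sex determination and dosage compensation genes 4 of 22 were bound, or 18.2% (interval 5.19 to 40.3%), 2.81-fold above other genes, which did not pass (Fisher's exact test, adjusted p = 0.12). In the 622 strongest IDR peaks 1 of 22 was bound (ratio 1.29). The bound members were dpy-30 (signal 144), dpy-27 (94.8), dpy-26 (83.8) and mix-1 (82.6), which all encode proteins of the dosage compensation complex. Their summits lay 327, 641 and 114 bp upstream of the starts of dpy-30, dpy-27 and dpy-26, and 36 bp downstream of that of mix-1, and none had ATCGAT within 50 bp. By signal value the peaks of dpy-30, dpy-27, dpy-26 and mix-1 ranked 320, 665, 1022 and 1288 in replicate 1. In replicate 2 they ranked 840, 7429, 6177 and 564, and 790 peaks of that list had a q-value under 0.05.

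Of the 6 ONECUT genes, ceh-38 alone was bound by the promoter criterion; with the strongest peaks of replicate 2 alone 0 of 6 were bound, and with a window of 2000 bp upstream 2 of 6. Its peak (chromosome II, 6951544 to 6951849, signal 268) had its summit 17 bp downstream of a start and contained ATCGAT at 6951680 to 6951685, in the context CCATCAGTATCGATCGGTGTCT. ceh-21, ceh-39, ceh-41, ceh-48 and ceh-49 had no IDR summit in their windows. Upstream of ceh-39 (X, 1853874 to 1856172, minus strand), IDR summits at 1805 bp (signal 278) and 2672 bp (signal 286) lay beyond the window. Within 20 kb of the middle of ceh-39 there were 3 IDR peaks against a mean of 0.559 around the starts of other X genes (permutation p = 0.051), and 11 pooled relaxed peaks against 11.1 (permutation p = 1); counted from the start of ceh-39 these were 3 and 12 (permutation p = 0.051 and 0.92), a setting added after the data were seen. The strain carries a transgene of this factor, whose extent and copy number were not measured here. Within 10 kb the 3 IDR peaks stood against a mean of 0.298 (permutation p = 0.014), and within 50 kb there were 4 against 1.29 (permutation p = 0.097). With the strongest peaks of replicate 2 in place of the IDR peaks the ratio within 20 kb was 13.1 (permutation p = 0.0028). With those of replicate 1 it was 5.64 (permutation p = 0.054). The relaxed list of replicate 2 held 28 peaks within 20 kb against 11.6 (permutation p = 0.0020), but that of replicate 1 held 10 against 10.2. These settings were added after the data were seen.

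The ONECUT core ATCGAT was more frequent at summits than beside them, whereas the related core ATTGAT was less frequent. ATCGAT lay within 50 bp of 217 of 1244 IDR summits, or 17.4% (interval 15.4 to 19.7%), against 72, or 5.79% (4.56 to 7.23%), in windows 350 bp to the lower-coordinate side (ratio 3.01, exact McNemar test, p = 2.33e-20). ATTGAT, on either strand, lay at 73 summits, or 5.87% (4.63 to 7.32%), against 153 flanks, or 12.3% (10.5 to 14.3%; ratio 0.477, exact McNemar test, p = 4.69e-08). Without replicate 1, ATCGAT stood at 8.60% of the summits of replicate 2, 2.02 times its flank share (exact McNemar test, p = 1.61e-05). The ATTGAT ratio was 0.746 in the 2488 strongest pooled peaks and 0.737 within 100 bp of the summit (exact McNemar tests, p = 6.87e-04 and 1.83e-04). Among strong peaks, C37A2.8, nono-1, K04G2.10, Y17D7C.2 and set-10 had ATCGAT within 50 bp of the summit, and so did the weaker peaks at lin-35 and snb-1. In the 100 strongest peaks ATCGAT was present in 27% (interval 18.6 to 36.8%). In successive groups of 311 peaks, from strongest to weakest, its share was 21.5%, 16.7%, 14.5% and 17.0%. For ATCGAT alone, the median signal was 113 with and 108 without the core, a difference of 5.42 (permutation p = 0.12). The median signal of peaks with either core (111.7, 277 peaks) and without (108, 967 peaks) differed by 3.92 (permutation p = 0.19). In the 1244 strongest peaks of replicate 2 alone the difference was 1.33 (permutation p = 0.047) and in those of replicate 1 alone 1.80 (permutation p = 0.43), settings added after the data were seen; with windows of 100 bp it was 2.44 (permutation p = 0.32).

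**Figure D3:**
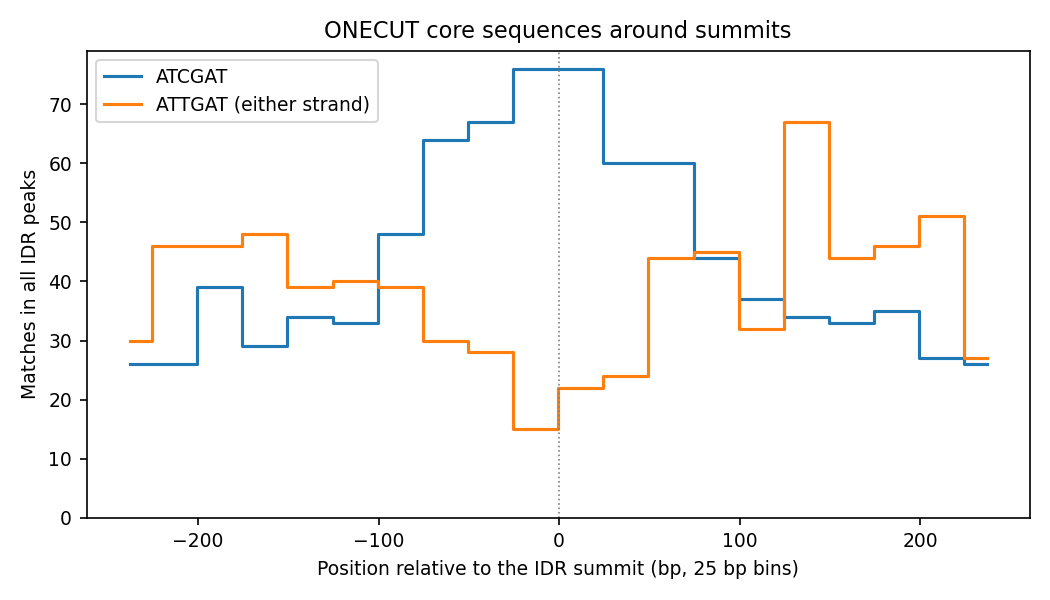
Number of ATCGAT and ATTGAT matches in 25 bp bins around the 1244 IDR summits. ATCGAT peaks at 76 matches in each of the bins beside the summit, where ATTGAT has 15 and 22.

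In the ranking of all hexamers ATCGAT stood at place 41. ACGCAG led, in 19.5% of summit windows against 1.81% of flanking windows, followed by GACGCA (17.9% against 2.29%), AGAGAC (20.7% against 3.30%), GAGCGC (17.1% against 1.77%) and ACGCGC (16.40% against 1.09%). GAGAGA was in 25.3% against 5.79%. A/T-rich hexamers were rarer at summits, such as AAAATT (18.1% against 42.2%) and TGAAAA (13.9% against 34.6%). At an adjusted p under 0.05 (exact McNemar test), 507 hexamers were more frequent at summits and 443 less frequent. With the strongest peaks of replicate 2 alone, 313 were more frequent and 206 less frequent, and ATCGAT ranked 142.

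Peaks were unevenly spread over the chromosomes. Chromosome V, with 25% of protein-coding genes, held 155 peaks, or 12.5% (interval 10.7 to 14.4%; exact binomial test, adjusted p = 4.18e-27). Chromosomes I and III each held 240 peaks, or 19.3%, against 14.4% and 13.2% of genes (exact binomial tests, adjusted p = 5.32e-06 and 7.07e-09). The pooled relaxed list, which includes background, held 18.3% of its peaks on I, 17.2% on III and 15.05% on V. These shares are closer to the IDR shares than the gene shares are. X held 218 peaks, or 17.5% (15.45 to 19.8%), 1.28 times its 13.7% share of genes (exact binomial test, p = 1.43e-04, adjusted 2.14e-04 over 6 chromosomes). Against its 17.7% share of genome length, X held no excess (ratio 0.992, exact binomial test, p = 0.91), nor did it against its 16.6% share of the pooled relaxed list (ratio 1.06, exact binomial test, p = 0.38). On the autosomes, 56.8% of peaks and 55.7% of gene starts lay in the middle part, between 25 and 75% of chromosome length (exact binomial test, p = 0.47). Chromosome V alone had 65.2% of its peaks there against 52.5% of its gene starts (exact binomial test, p = 0.0017), while the ratios on I, III and IV were 0.963, 0.943 and 0.958. Over all autosomes together, the strongest peaks of replicate 2 alone gave a ratio of 1.06 to the share of gene starts (exact binomial test, p = 0.025), and the IDR peaks gave 1.14 against 50% of length (exact binomial test, p = 1.39e-05).

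**Figure D4:**
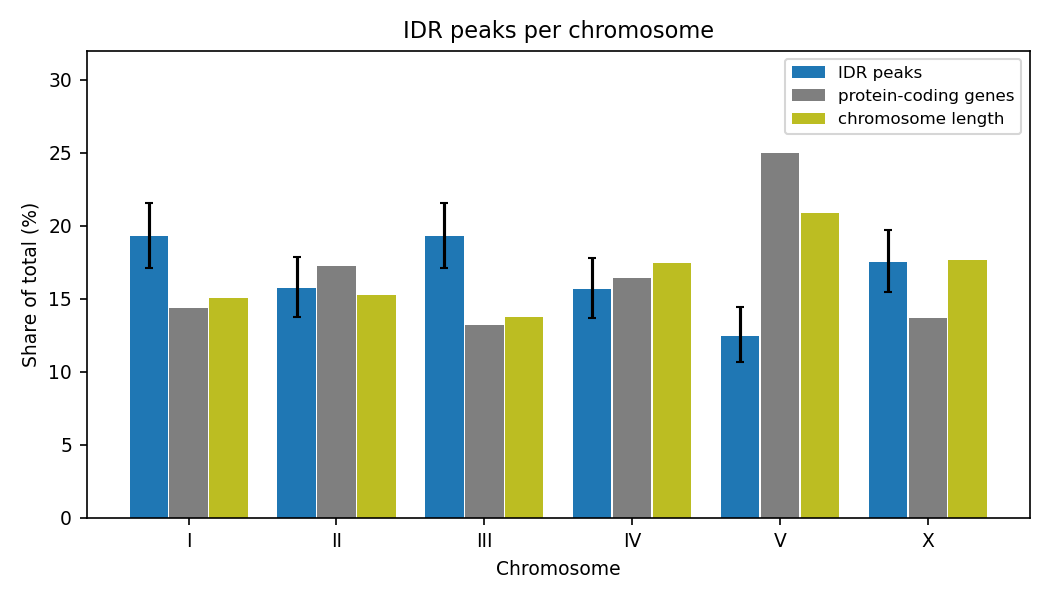
Share of IDR peaks per chromosome (blue, with exact 95% intervals) beside the share of protein-coding genes (grey) and of genome length (yellow). Chromosome V holds 12.5% of peaks and 25% of genes.

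tRNA genes were also near peaks. Of 612 tRNA genes 33, or 5.39% (interval 3.74 to 7.49%), had an IDR summit within 200 bp, against 0.627% for placed positions (ratio 8.59, permutation p = 0.020, the smallest possible with 100 placements). The ratio was 14.5 with the strongest peaks of replicate 2 alone, 4.53 with those of replicate 1 alone, and 4.74 with a window of 500 bp (permutation p = 0.020 for each). Placements were uniform along each chromosome, whereas IDR summits lay mainly near protein-coding starts.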

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

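Leaving out a replicate was added after the data were seen for the hexamer ranking, for motif and signal, and for ceh-39, as were the same centres for all ceh-39 windows; the other alternatives were chosen before the data were examined. Of the main results under their alternatives, 64 values kept their side of the threshold or, where no test applied, stayed within a fixed limit. Those that did not are listed here, and their cause was not tested. Not all of the 64 kept their direction. Around ceh-39 the pooled relaxed ratio was 0.987, but 1.61 within 10 kb and 1.08 with windows centred on gene starts (permutation p = 0.39 and 0.92). The X share of peaks was 0.992 times its share of genome length, a reversal, and 1.06 times its share of the pooled relaxed list. The autosome centre ratio was 1.14 against 50% of length, and 1.02 to 1.06 with the strongest peaks of either replicate alone. The share of IDR peaks found among the strongest of replicate 1 was 82.3% when 50% of the peak had to be covered and 99.8% for the 622 strongest IDR peaks; for replicate 2 it was 52.6% with summits within 100 bp and 75.6% for the 622 strongest. The difference in median signal with and without a core was 1.33 to 1.80 with either replicate alone. Around ceh-39 the IDR peak ratio was 10.1 within 10 kb and 5.64 to 13.1 with either replicate alone, and the relaxed ratio was 0.977 to 2.42, a reversal in replicate 2. Hexamers more frequent at summits numbered 313 to 527 with either replicate alone. For single gene lists 125 values kept their call, 7 gained one and 4 lost one, and lists past the threshold numbered 3 to 6 against 4. With no read counts, the effect of depth could not be estimated.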

Other observations

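Gene families in this part were chosen after the bound genes had been seen, so their shares are given without p-values. The snoRNA, snRNA, miRNA and rRNA classes were not among the planned tests, so their p-values serve as description only. Tests of ATCGAT at ribosomal protein promoters and of replicate ranks with and without ATCGAT were chosen after their results had been seen. So were the tests of the peaks around ceh-39 and the common window centres for ceh-39. Tests of base composition and of families by chromosome followed the main results but were written down before they were run.

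Shares of bound genes were listed for 15 families, and those of RNA processing, translation and energy supply stood above the 6.48% of all protein-coding genes. Splicing factor and snRNP genes were bound in 18 of 32 cases, or 56.2%, among them snr-2 (signal 314), prp-8 (250.2) and snr-4 (231). Translation initiation and elongation factor genes were bound in 16 of 39 cases, or 41.03%, with iff-2 (384), eef-1A.1 (308) and eef-1A.2 (290.3) the strongest. Genes of the respiratory chain had 13 of 38 bound, or 34.2%, led by cox-5A (344) and cox-6B (231). Proteasome subunits had 9 of 33 bound, with rpn-3 (246) the strongest, mitochondrial ribosomal proteins 14 of 70, vacuolar ATPase subunits 5 of 20 and aminoacyl-tRNA synthetases 4 of 32. A peak in the windows of several genes was counted for each of them. The same peak made both rsp-1 and rsp-2 bound, and the prp-8 peak also made the BATH gene bath-42 bound. Families were not counted with nearest-start assignment.

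Other families had low shares. Chemoreceptor genes had 6 of 1316 bound, or 0.456%, C-type lectins 4 of 240 and F-box genes 12 of 322. No cytochrome P450 gene of 74 and no UDP-glucuronosyltransferase gene of 67 was bound, and BATH and MATH domain genes had 1 of 73 bound. Among small RNA genes, 33 of 346 snoRNA genes, 14 of 129 snRNA genes and 8 of 261 miRNA genes had an IDR summit within 200 bp, against 0.679%, 0.628% and 0.605% of such genes with placed positions (permutation p = 0.020 for each). Of 20 rRNA genes 0 had one, against 0.85% (permutation p = 1). The placed positions were uniform along each chromosome and did not follow the closeness of IDR summits to protein-coding starts.

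The core ATCGAT marked a minority of summits. Its summit-to-flank ratio was 2.93 (95% bootstrap interval 2.39 to 3.597), and 0 of 101 other hexamers made of the same bases had a higher one; the highest that is not a shifted copy of the core, TACGTA, had 1.85. This argues against single-base composition alone as the source of the ATCGAT excess. The hexamers were not matched for neighbouring bases, and ATCGAT and TACGTA both hold the dinucleotide CG. Hexamers with CG led the ranking, such as ACGCAG (ratio 10.8) and ACGCGC (15.1). A contribution of CG content or of promoter sequence was therefore not excluded. The ratio of ATTGAT, 0.507, was exceeded by 31 of 59 hexamers of its bases, so its deficit is no larger than that of other hexamers of the same bases. At ribosomal protein promoters ATCGAT was in 3.45% of 58 peaks, against 17.0% of 875 peaks at other promoters (Fisher's exact test, p = 0.0048), which argues against this core as what brings the factor there. Binding there without the core, by way of other proteins or open chromatin, may account for these peaks and was not tested, and neither was a biological difference, since the series has 1 group.

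The replicates differed in how strongly they held ATCGAT peaks. With the 1176 shared IDR peaks ranked within each replicate, the median rank in replicate 1 minus that in replicate 2 was -191.5 for 204 peaks with ATCGAT and 15 for the others, a difference of -206.5 (permutation p = 1e-05, the smallest possible), so peaks with the core stood higher in replicate 1. With these peaks split at their median GC content, the difference was -226 in the lower part and -176 in the higher part (permutation p = 1e-05 and 0.0019). Each part still spans a range of GC content, so this split cannot exclude a contribution of base composition. Of the strongest peaks, 619 were found in replicate 1 and not among those of replicate 2. ATCGAT was in 23.3% of them, against 7.11% of their flanks (exact McNemar test, p = 3.41e-17). Of the 616 in replicate 2 and not among those of replicate 1, 4.55% had it, against 3.73% (exact McNemar test, p = 0.58). Promoter windows held 74.8% of the 619 summits and 54.5% of the 616. The strongest peaks of replicate 2 include some that miss a q-value of 0.05, so the 2 sets are not of like stringency. A candidate explanation is a weaker enrichment of the factor in replicate 2, whose list held 790 peaks at a q-value under 0.05; a different mix of embryo stages stays open and was not tested.

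Peaks with a low q-value were numerous around ceh-39, the gene of the factor that the transgene of this strain expresses. At a q-value under 0.05, replicate 1 held 9 peaks within 20 kb of the middle of ceh-39 against a mean of 1.47 around the starts of other X genes, and replicate 2 held 6 against 0.369 (permutation p = 0.0042 and 0.0028; 0.0058 and 0.0036 with all windows centred on gene middles). Extra copies of the region would raise both replicates in this way and are a candidate explanation, but only if the control lacked them, which is not given in the sources used here, and copy number was not measured. Binding of the factor at its own locus would too, and the 2 cannot be told apart. Of these 15 peaks, some of which mark the same site in both replicates, 0% had summits in coding sequence or a 3′ UTR. Only 1.76% did on the rest of X (Fisher's exact test, p = 1), so the test could not decide. None of the 15 lay between 1000 bp upstream and 200 bp downstream of the gene starts of ceh-39, ceh-21 or ceh-41. The nearest upstream of ceh-39 lay at 1804 bp in replicate 1 and 1726 bp in replicate 2. Between 1846518 and 1857049 on X, the stretch that holds ceh-41, ceh-21 and ceh-39, no list had a summit, the relaxed lists included. Extra copies of this whole stretch could be expected to raise it too. The extent of the transgene was not measured, so the cause of this gap was not tested.

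The low share of peaks on chromosome V was tested against 8 gene families of low share, 2517 genes of which 1349 are on V. With these families left out of the background, V held 0.597 times its share of genes (exact binomial test, p = 1.21e-14) and X 1.17 times (exact binomial test, p = 0.014), against 0.498 and 1.28 with all genes, so these families alone do not account for either share.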
